A study of Equus caballus with 8 samples.

How the data were processed

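Messenger RNA was measured by sequencing in endometrial biopsies of 4 mares. Each mare gave 1 biopsy on Day 12 of pregnancy and 1 on Day 12 of the oestrous cycle, so the 8 libraries form 4 pairs. Per the labels' protocols, ovulation was induced with 1500 IU of human chorionic gonadotropin, the uterus was flushed before the biopsy, and RNA integrity numbers ran from 8.3 to 9.2. Libraries were made from poly(A) RNA, starting from 5 µg of total RNA, with fragments of about 200 bp and 15 PCR cycles, per the labels' protocols. The kit as described there does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart.

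The authors deposited a table of raw read counts per gene, with 24942 NCBI Gene IDs and 1 column per library. Trimmomatic 0.32.2 and HISAT2 2.0.3 are named in the submitters' processing notes. The genome build, the annotation and the counting tool are not given in the sources used here. The authors also deposited a table of scaled signal values for 14037 of these genes. Tested on the values, that second table holds CPM values (counts scaled to library size) after scaling by the trimmed mean of M values (TMM), with 100% of the values within a relative tolerance of 1e-06. Its genes are the 14037 with more than 2 CPM in at least 2 libraries. It was used for this check and for 1 alternative. No column of values per sample was left unused (0 columns).

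Gene names came from a RefSeq gene table of a telomere-to-telomere horse assembly, matched by Gene ID. Of the 24942 IDs, 21420 (85.9%) matched, and 18001 of these carry a symbol other than a placeholder. No coordinates are given, because the build behind the counts is not known and no genome was used here. The gene span, meaning the distance from a gene's start to its end in that table, served only as a property of genes in 1 test.

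Total counts per library ran from 9.81 to 16.7 M. The pregnant library of mare 1 had 9.81 M and the other 7 libraries had 15.5 to 16.7 M. A count of 0 allows up to 3 counts, which is 0.306 CPM in the pregnant library of mare 1 and 0.18 to 0.194 CPM in the others. The libraries carry no molecular identifiers, so such limits cover counting error only. No pair of libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom over genes with at least 20 counts being 24.6.

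Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 15342 genes holding 99.9% of the counts of each library, and libraries were scaled by TMM. The quasi-likelihood F-test (robust setting) compared pregnancy with the cycle in a model with the mare as a block, since the series' design text states that both biopsies came from every mare. P-values were adjusted by the Benjamini-Hochberg method, and a gene with an adjusted p below 0.05 is said to have risen, fallen or changed. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled and are given as mean ± SD over 4 mares. Differences between mares were tested in the same model with the 3 mare terms together. Same-mare libraries deviated together from their group means, with correlations across genes of 0.54, 0.38, 0.48 and 0.47 for mares 1 to 4, against at most -0.02 between different mares.

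Fixed before the data were examined were 34 gene lists for uterine functions and for the cell types a biopsy can hold, the designs, the alternatives and the rule for the genes named. Lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 32 lists. Camera was repeated with a correlation estimated per list, and fry was run on the same values. No Gene ID matched the mitochondrially encoded genes, and the erythrocyte list had 3 tested genes, so those 2 lists were not tested. The genes named are the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 1 CPM and the same direction in 4 mares; the 4 risers and 4 fallers with the smallest p besides these; 12 genes much discussed for maternal recognition of pregnancy, whatever their result; and per list up to 4 called members with the smallest p, or up to 2 of the most abundant where none was called. Some genes that this rule picks are not reported here, and the test for outlying libraries leaves them out. Some of the 12 come from earlier equine work that may have used the same mares.

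The tests were checked on simulated data, with counts drawn 5 times for the 15342 genes from the fitted means and library sizes and 200 genes changed. For the comparison of pregnancy with the cycle, the test with the mare block recovered 55.8% of genes changed 1.5-fold, 87.2% of those changed 2-fold and 97.9% of those changed 4-fold. On average 10.4% of its calls were false when each gene kept its own estimated dispersion, against 5.23% when dispersions lay on the fitted trend. The false calls had a median dispersion 4.24 times the trend. With each gene's own dispersion, the fit without the mare block made 0% false calls. It recovered 6.57% of genes changed 1.5-fold, 56.1% of those changed 2-fold and 90.3% of those changed 4-fold. False calls averaged 11.1% with limma-voom and 12.4% with DESeq2. With 30 random genes raised 1.5-fold as an added list, camera with the preset correlation called 0 of the 32 unshifted lists in each simulation. It called the shifted list in 5 of 5. The F-test between mares called at most 26 genes when mares did not differ. These simulated genes vary independently, which real genes do not. All 200 changed genes had a mean of at least 1 CPM, whereas 2565 genes were called in the real libraries. The shares recovered and false depend on how many genes change.

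Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test with trended dispersion, the robust setting, the 10 most abundant genes left out of the scaling, the fit without the mare block, each mare left out in turn, and other thresholds. Thinning every library to the 9.81 M counts of the shallowest and keeping only the genes of the authors' scaled table were chosen after seeing the data.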

Results

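Endometrial RNA was sequenced from 4 mares, each sampled on Day 12 of pregnancy and on Day 12 of the oestrous cycle, giving 4 pregnant and 4 cyclic libraries. Total counts were 16.1 ± 0.456 M (SD, n = 4) in the cyclic group and 14.9 ± 3.39 M (SD, n = 4) in the pregnant group, where the library of mare 1 was the shallowest at 9.81 M. The mare, with 3 degrees of freedom, accounted for 53.5% of the sum of squares of log2 CPM on average over genes (median 54.8%), the state, with 1, for 23.8% (median 15.97%), and the remainder, with 3, for 22.7% (median 17.0%).

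The comparison of the pregnant with the cyclic state asked which transcripts of the endometrium differ when a conceptus is present at the time of maternal recognition of pregnancy. SLC36A2, a proton-coupled transporter of small amino acids, rose from 0.764 ± 0.808 to 53.5 ± 33.8 CPM, and WNT7B, a secreted Wnt ligand, rose from 0.538 to 31.8 CPM (means of 4 mares, ± SD where given). LAMB3, a chain of the basement membrane laminin 332, rose 4.91-fold, and STC1, a secreted glycoprotein hormone, rose 2.92-fold. ESR1, the oestrogen receptor alpha, fell from 287 ± 81.9 to 179 ± 26.3 CPM, and PTGFR, the receptor of prostaglandin F2 alpha, fell from 19.2 ± 5.87 to 7.01 ± 2.27 CPM. In all, 2565 of 15342 genes changed, 1309 of them higher and 1256 lower in pregnancy, and 2548 moved in the same direction in each of the 4 mares. A test of differences within 4 mares favours such genes, so this agreement is no separate evidence. A change of at least 2-fold was seen for 268 risers and 92 fallers. The count was 389 (268 higher, 121 lower) in the fit without the mare as replicate block and 1266 (653 higher, 613 lower) without mare 1, whose pregnant library was the shallowest.

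The largest rises were led by SLC36A2 (Gene ID 100071541), with a log2 fold change of 6.17 ± 0.43 (SE; adjusted p = 0.00229), and WNT7B (100053027), with 5.85 ± 0.14 (adjusted p = 1.07e-07). IGFBP1 (100034154), a binding protein of insulin-like growth factors, had a log2 fold change of 5.43 ± 0.42 and reached 5.24 ± 4.39 CPM in pregnancy. Its cyclic mean of 0.111 CPM was below what 3 counts give in a library, as was that of the fatty acid desaturase family member FADS3 (100059870; 0.172 CPM), so their folds of 43.1 and 14.8 rest on few cyclic reads. Without mare 4, whose pregnant value of 10.7 CPM was the highest, the log2 fold change of IGFBP1 was 4.67. TMEM213 (100066723) rose from 0.980 ± 0.654 to 25.0 ± 13.1 CPM, and ATP6V0A4 (100064797), a subunit of the vacuolar proton pump, rose from 1.81 ± 0.695 to 22.0 ± 9.51 CPM. CKMT1B (100056283), a mitochondrial creatine kinase, rose 17.0-fold. Its value is uncertain if the unstated annotation holds a near-identical copy such as CKMT1A, since reads may then be divided between the genes. Smallest in p besides these were LAMB3 (100056564; log2 fold change 2.30 ± 0.10), VIT (100070306), an extracellular matrix protein (1.71 ± 0.10), ANG (100034041), the ribonuclease angiogenin (1.48 ± 0.09), and SERPING1 (100066476), the C1 inhibitor (1.04 ± 0.07), with adjusted p from 1.64e-05 to 1.37e-04.

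The falls were smaller. The largest was that of H2BC6 (100053695; log2 fold change -3.02 ± 0.39), a histone gene whose reads may be shared with other histone genes, so its value is uncertain. GRXCR2 (100061120) fell from 2.23 ± 1.21 to 0.330 ± 0.152 CPM, CRTAC1 (100060874) from 4.98 ± 2.17 to 0.960 ± 0.431 CPM, and NT5C1A (100054191), a cytosolic 5′-nucleotidase, from 7.59 ± 3.39 to 1.77 ± 0.765 CPM. FXYD4 (100629797), a regulator of the sodium pump, fell from 40.4 ± 18.1 to 8.19 ± 5.28 CPM (adjusted p = 0.0423), a call kept in 11 of 16 alternatives and lost without mare 1, 2 or 4, without the mare block and without the low-count filter (adjusted p for FXYD4 up to 0.143). SPMAP2L (102149408), PTAR1 (100056335) and FSTL4 (100063004) fell 3.54-fold, 3.35-fold and 3.09-fold. The call of SPMAP2L was lost without mare 1 (adjusted p = 0.0962) and without mare 3 (0.0508). Smallest in p were CTSL (100061532), the protease cathepsin L (log2 fold change -1.42 ± 0.08), SESN3 (100061072), a stress-inducible sestrin (-1.45 ± 0.09), SLC38A1 (100050256), a glutamine transporter (-1.06 ± 0.07), and PTGFR (100009714; -1.46 ± 0.10). Without the mare block the adjusted p was 0.364 for CTSL, 0.124 for H2BC6, 0.204 for PTAR1, 0.0565 for FSTL4 and 0.0739 for SPMAP2L, the highest over the alternatives for each but SPMAP2L.

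**Figure D1:**
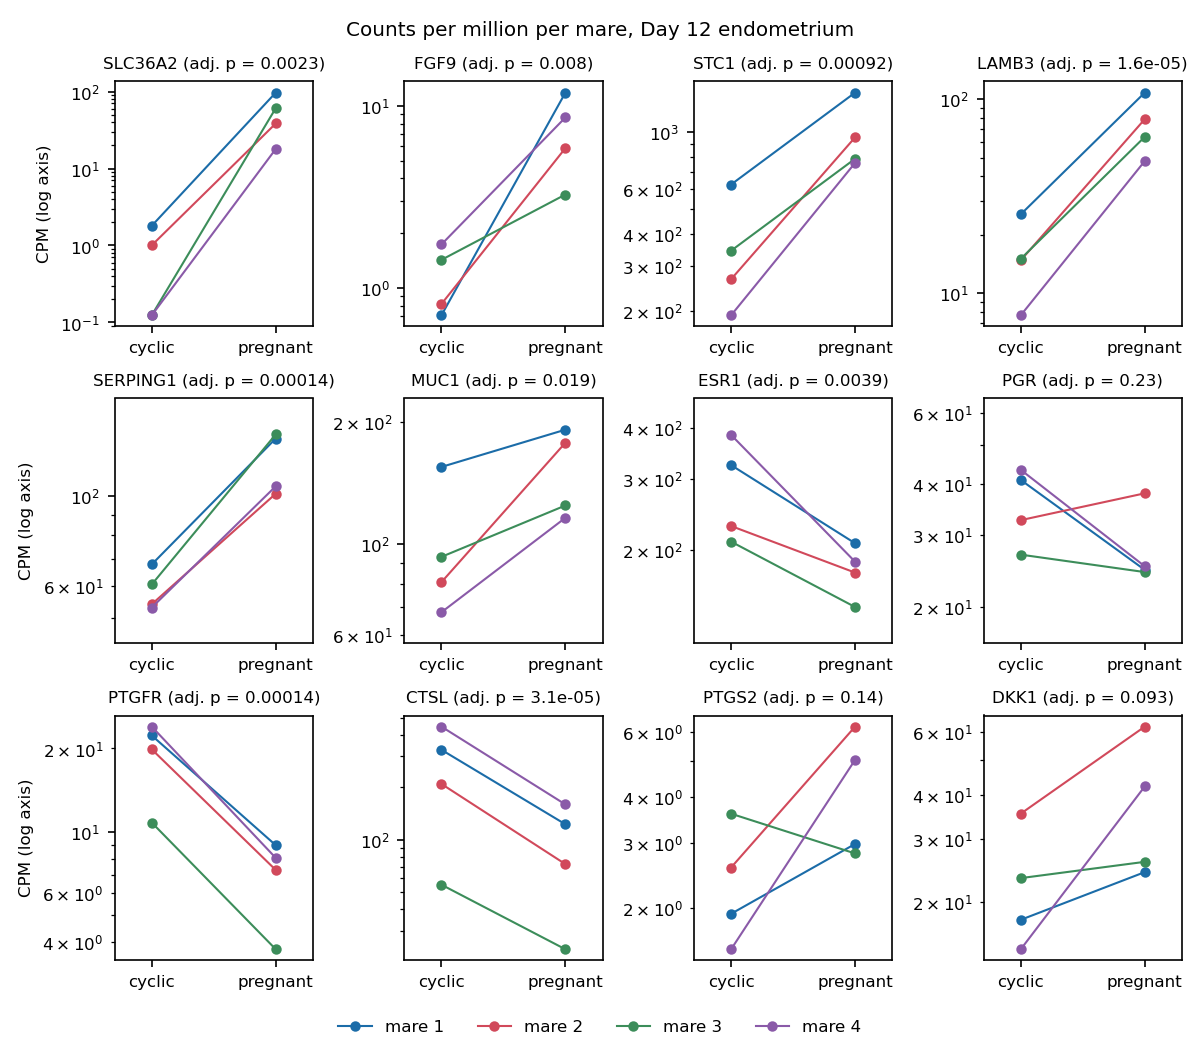
TMM-scaled CPM on a log axis for 12 genes in the cyclic and the pregnant library of each mare, joined by a line per mare, with the adjusted p of the test with the mare block above each panel. SLC36A2, FGF9, STC1, LAMB3, SERPING1 and MUC1 were higher and ESR1, PTGFR and CTSL lower in pregnancy in 4 of 4 mares, while PGR and PTGS2 went both ways and DKK1 missed the threshold.

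Picked for their place in maternal recognition of pregnancy were 12 genes, some from earlier equine work that may have used the same mares. They are thus not an independent test. Of the 12, 11 were tested and 6 changed, against 16.7% of all genes tested. Besides SLC36A2, ESR1 and PTGFR, these were FGF9, a fibroblast growth factor, which rose from 1.17 ± 0.491 to 7.40 ± 3.68 CPM, STC1, which rose from 357 ± 189 to 980 ± 308 CPM, and the cell surface mucin MUC1, which rose from 99.3 ± 38.5 to 153 ± 37.6 CPM. The progesterone receptor PGR had 36.0 ± 7.63 CPM in the cycle and 28.1 ± 6.66 CPM in pregnancy (adjusted p = 0.234), and it was lower in 3 of 4 mares. PTGS2, the inducible prostaglandin synthase, had 2.41 ± 0.897 and 4.25 ± 1.64 CPM (adjusted p = 0.136), and the prostaglandin E synthase PTGES 44.2 ± 8.26 and 44.8 ± 5.69 CPM (adjusted p = 0.846). IGF1 was lower in 4 of 4 mares (adjusted p = 0.0851), and the Wnt antagonist DKK1 was higher in 4 of 4 mares, at 22.8 ± 9.09 and 38.6 ± 17.6 CPM (adjusted p = 0.0930). OXTR, the oxytocin receptor, matched no Gene ID and was not analysed here. Without the mare block the adjusted p was 0.103 for ESR1, 0.0758 for STC1 and 0.271 for MUC1, the highest over their alternatives, and leaving out mare 2 gave 0.0527 for FGF9. PGR passed in 2 of 16 alternatives, without mare 2 and in the likelihood ratio test (adjusted p 0.0386 to 0.522 over its alternatives), PTGS2 passed without mare 3 and in the likelihood ratio test (0.0129 to 0.382 over its alternatives), and DKK1 passed in 6 of 16, among them DESeq2, limma-voom and the likelihood ratio test (1.85e-06 to 0.319 over its alternatives).

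The gene lists asked whether functions and cell types moved together. With the preset correlation, 17 of 32 lists changed, 16 higher and 1 lower in pregnancy. With a correlation estimated per list 0 lists passed (4 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, passed 13, of which 9 were among the 17. It also passed the nutrient transporter, ion, water and calcium, adhesion and epithelial lists, which the main test did not. Of the 17, fry did not pass growth factors, extracellular matrix, cholesterol synthesis, immediate early, ribosomal protein, smooth muscle, T and NK, or macrophage and dendritic lists. The counts of members below, over all genes tested, do not depend on the choice of list test, and each is followed by the count adjusted over the list alone. Over all 15342 genes tested, 1309 rose and 1256 fell. Beside that share, 1 of 23 macrophage and dendritic, 3 of 58 ribosomal protein and 2 of 25 immediate early genes rose, which is no excess.

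Markers of endothelium rose most widely. Of 22 tested, 17 rose and 0 fell (20 and 0 adjusted over the list alone), among them the tight junction gene CLDN5 (from 6.11 ± 1.61 to 18.4 ± 4.94 CPM), the cadherin CDH5 (1.83-fold), ECSCR (2.24-fold) and PECAM1 (1.84-fold). The list passed with adjusted p = 2.96e-11, and it had adjusted p = 0.356 with an estimated correlation. Of 30 angiogenesis genes, 17 rose and 1 fell (18 and 2 adjusted over the list alone). ANG, PDGFRB, a receptor of pericytes and stroma (1.62-fold), and TIE1 (1.87-fold) rose, and the endothelin receptor EDNRB fell from 206 ± 41.2 to 113 ± 35.0 CPM. Lists share genes, so their counts overlap: TIE1 is also in the endothelial and PDGFRB in the stromal list. The stromal and extracellular matrix lists share COL1A1, DCN and LUM. Adjusted p was 4.98e-08 for angiogenesis and 0.356 as adjusted p with an estimated correlation. Of 24 stromal markers, 13 rose and 1 fell (15 and 1 adjusted over the list alone), with DPT, a matrix protein, at 178 ± 38.7 and 366 ± 38.1 CPM, and MFAP4 (2.40-fold), SCARA5 (1.59-fold) and ASPN (1.70-fold). Of 17 smooth muscle markers, 8 rose and 1 fell (11 and 1 adjusted over the list alone), with calponin CNN1 at 2.26 ± 1.58 and 10.2 ± 3.11 CPM, LMOD1 (1.77-fold) and RGS5 (1.55-fold) higher, and phospholamban PLN lower (log2 fold change -1.07 ± 0.20). Adjusted p was 1.89e-05 for stroma and 8.80e-05 for smooth muscle, and both were lost, at adjusted p = 0.391 and adjusted p = 0.483 with an estimated correlation. Of 45 extracellular matrix genes, 15 rose and 2 fell (20 and 2 adjusted over the list alone), with elastin ELN (2.31-fold), TIMP1 (1.78-fold) and TGM2 (1.97-fold) among the risers. That list had adjusted p = 6.97e-04, and adjusted p = 0.573 with an estimated correlation.

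**Figure D2:**
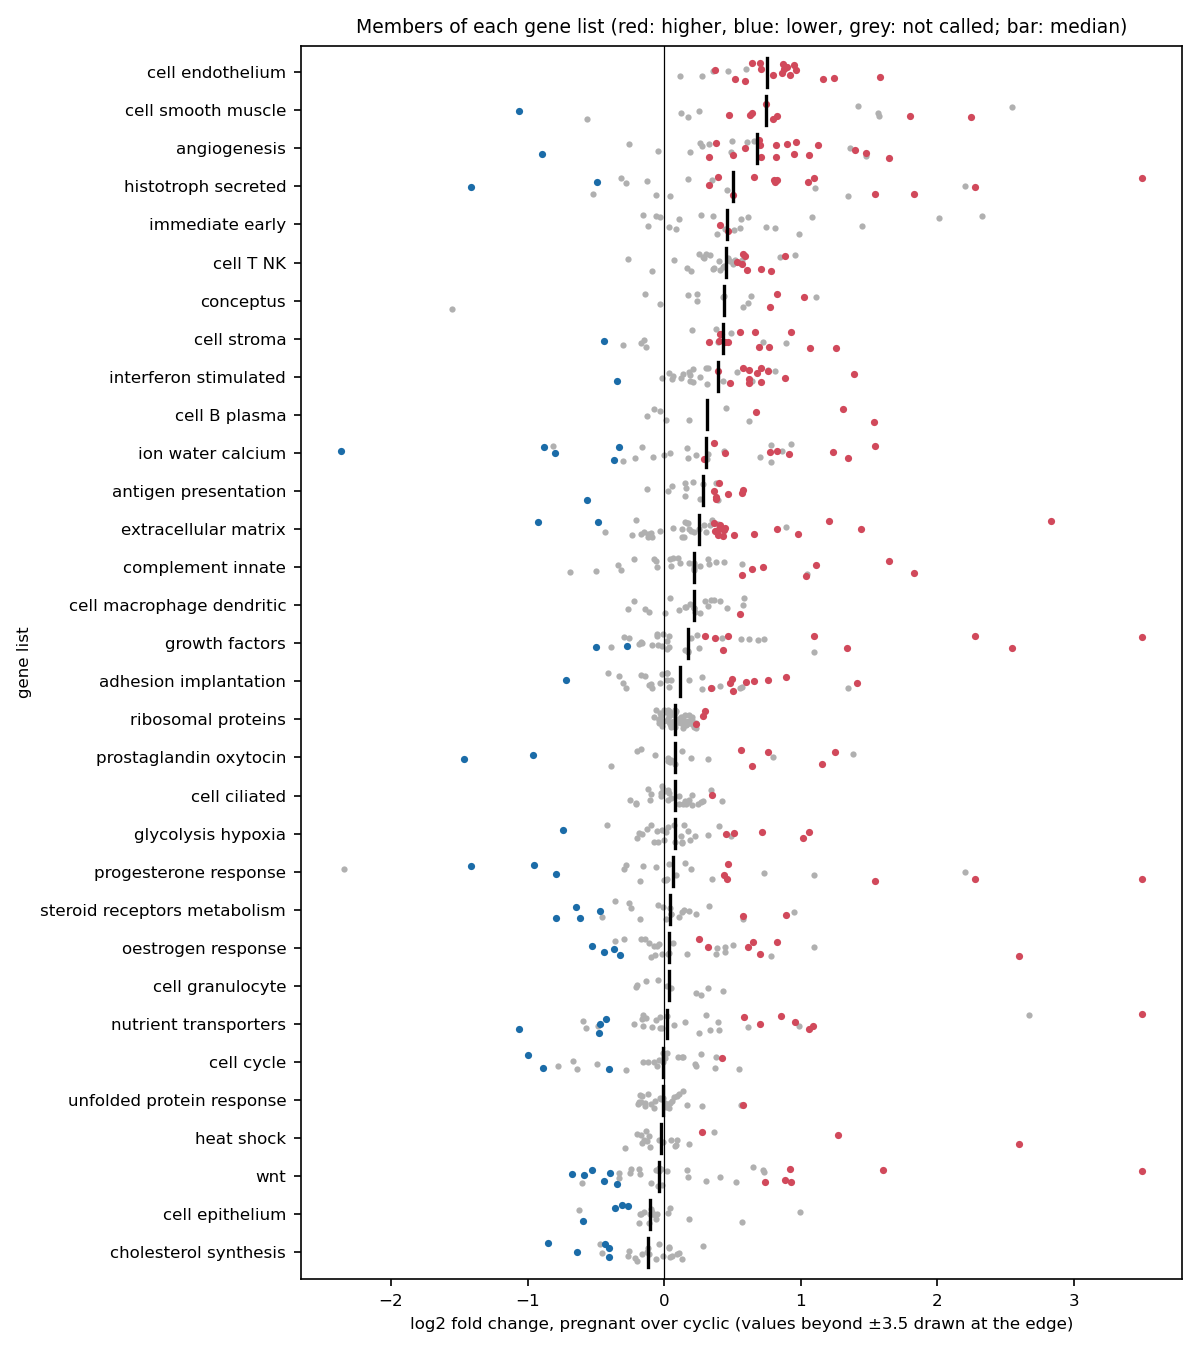
Log2 fold change of each member of the 32 tested lists, with lists ordered by their median (black bar), red points for risers, blue points for fallers and grey points for genes that did not pass; values beyond the axis limits are drawn at the edge. The endothelial list has 17 red points of 22, and the cholesterol synthesis list, at the bottom, has 5 blue points of 26.

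Epithelial markers did not share these rises. Of 22, 0 rose and 4 fell (0 and 4 adjusted over the list alone), namely the keratins KRT7 (log2 fold change -0.59 ± 0.10) and KRT18 (-0.31 ± 0.08), PROM1 and ESRP2, while the list itself missed the threshold (adjusted p = 0.0563). Its median was below 0 in 4 of 4 mares, and the list passed by fry (adjusted p = 0.0335) and by camera without mare 1 (adjusted p = 0.0497). The calls of KRT18 and ESRP2 were lost with library totals in place of TMM, in the likelihood ratio test, without the mare block and without mare 1, 2 or 4 (highest adjusted p 0.471 and 0.325). Of 30 ciliated cell markers, 1 rose (1 adjusted over the list alone), TPPP3 (1.28-fold), and the list did not pass (adjusted p = 0.228).

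Among immune cell markers, T and NK cell genes rose in 8 of 32 cases and fell in 0 (10 and 0 adjusted over the list alone), with SKAP1 (1.49-fold), the chemokine CCL5 (1.48-fold), CD3D (1.53-fold; passing in 11 of 16 alternatives) and the granzyme GZMK (1.85-fold). Mare 2 carried much of this, with a T and NK median log2 ratio of 0.95 against 0.17 to 0.47 in the others, and without it the list median was 0.25 in place of 0.46. Of 10 B and plasma cell markers, 3 rose (3 adjusted over the list alone), PRDM1 from 11.9 ± 1.33 to 19.2 ± 3.43 CPM, CD79A and BLK, the last on 2 to 12 counts per cyclic library and passing in 7 of 12 alternatives (adjusted p up to 0.249). Of 23 macrophage and dendritic cell markers 1 rose (1 adjusted over the list alone), the lipopolysaccharide co-receptor CD14 (1.47-fold). The lists passed with adjusted p of 8.79e-06, 0.0449 and 0.0382 for T and NK, B and plasma, and macrophage and dendritic cells, and with an estimated correlation had adjusted p = 0.573, adjusted p = 0.367 and adjusted p = 0.624. The B and plasma call held in 3 of 12 alternatives (up to 0.114 without a mare) and the macrophage and dendritic call in 7 of 12 (up to 0.257 without mare 2). Of 10 granulocyte markers 0 changed (0 adjusted over the list alone; adjusted p = 0.794), and the tryptase TPSB2 had 120 ± 96.1 CPM in the cycle and 123 ± 78.3 CPM in pregnancy, and KIT had 11.7 ± 8.42 and 15.8 ± 10.1 CPM. Of the 3 erythrocyte genes tested, GYPC rose 1.74-fold.

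**Figure D3:**
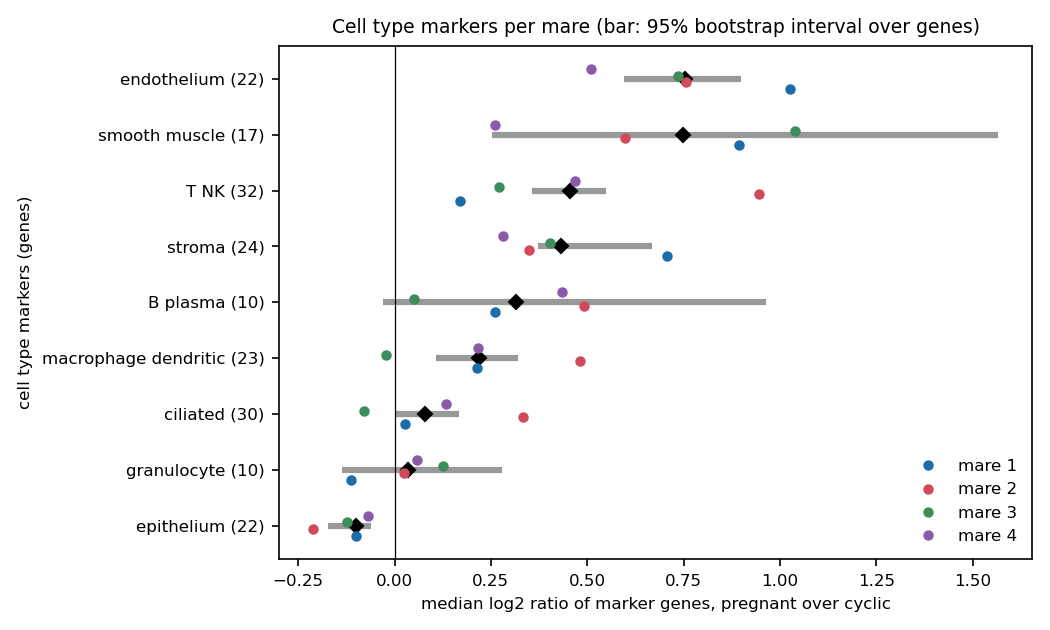
Median log2 ratio of pregnant over cyclic for the markers of 9 cell types, with 1 coloured point per mare, a black diamond for the median of the fitted log2 fold changes and a grey bar for its 95% bootstrap interval over genes. Endothelial, smooth muscle, stromal, T and NK, and B and plasma cell medians lie above 0 in 4 of 4 mares, and the epithelial median lies below 0 in 4 of 4.

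Of 33 interferon-stimulated genes, 12 rose and 1 fell (15 and 1 adjusted over the list alone), with IFI6 from 23.5 ± 3.12 to 37.6 ± 4.37 CPM, the antiviral GTPase MX1 (1.54-fold), CMPK2 (1.64-fold) and IFIT3 (1.54-fold). Of 19 antigen presentation genes, 7 rose and 1 fell (11 and 1 adjusted over the list alone). The invariant chain CD74 (1.49-fold), the class II transactivator CIITA (1.48-fold) and the immunoproteasome subunit PSMB8 (log2 fold change 0.38) rose, and the aminopeptidase ERAP2 fell (log2 fold change -0.56 ± 0.11). Of 32 complement and innate genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with C1R (1.66-fold), C1S (1.56-fold) and SERPING1. Adjusted p was 1.37e-06 for the interferon list, 7.85e-04 for antigen presentation and 5.05e-04 for complement, and with an estimated correlation they had adjusted p = 0.367, adjusted p = 0.362 and adjusted p = 0.356.

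Transcripts of proteins secreted into the uterine lumen rose in part. Of 27 histotroph genes, 13 rose and 2 fell (19 and 3 adjusted over the list alone). LCN2, a siderophore-binding lipocalin, rose from 39.1 ± 7.54 to 146 ± 62.0 CPM, beside IGFBP1 and STC1, and CTSL fell. The most abundant member by far, P19, had 47568 ± 10572 CPM in the cycle and 37636.5 ± 4291 CPM in pregnancy. P19 was lower in 4 of 4 mares and missed the threshold over all genes (adjusted p = 0.0870), but passed over the list alone (0.0246). The counts of risers therefore do not mean a higher total of these transcripts. The histotroph list had adjusted p = 1.24e-04, and adjusted p = 0.356 with an estimated correlation. Of 39 growth factor genes, 9 rose and 2 fell (12 and 3 adjusted over the list alone), with IGF2 from 9.83 ± 4.35 to 25.0 ± 10.7 CPM, the hepatocyte growth factor receptor MET (1.35-fold) and TGFB1 (1.38-fold). This list was near the threshold (adjusted p = 0.0449), with adjusted p = 0.597 with an estimated correlation. It held in 5 of 12 alternatives and was lost with library totals, with the stricter filter, after thinning and without mare 1 or 4 (up to 0.133).

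Hormone-related lists held members that moved both ways and did not pass. Of 33 oestrogen response genes, 7 rose and 4 fell (7 and 4 adjusted over the list alone; list adjusted p = 0.313), with the chemokine CXCL12 (1.57-fold) and the carbonic anhydrase CA12 (1.78-fold) higher and the nuclear receptor cofactor NRIP1 (log2 fold change -0.53 ± 0.07) and OLFM1 (-0.44 ± 0.09) lower. Of 26 progesterone response genes, 6 rose and 3 fell (10 and 5 adjusted over the list alone; 0.357), and the hedgehog ligand IHH fell from 1099 ± 244 to 568 ± 141 CPM. Of 25 steroid receptor and metabolism genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; 0.794). The steroid reductases SRD5A3 (-0.47 ± 0.06) and SRD5A1 (0.90 ± 0.18) moved in opposite directions, and HSD11B2, which inactivates cortisol, fell from 18.1 ± 4.15 to 10.3 ± 0.513 CPM. Of 21 prostaglandin and oxytocin genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone; 0.185). The prostaglandin transporter SLCO2A1 (2.38-fold) and prostacyclin synthase PTGIS (1.56-fold) rose, and the oxytocinase LNPEP fell from 68.4 ± 19.2 to 34.6 ± 8.14 CPM along with PTGFR.

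Transport and adhesion genes also moved both ways. Of 35 nutrient transporters, 7 rose and 4 fell (8 and 4 adjusted over the list alone; list adjusted p = 0.331), with the glucose transporter SLC2A1 at 144 ± 38.3 and 298 ± 78.0 CPM and the neutral amino acid transporter SLC1A4 (1.81-fold) higher, and SLC38A1 lower. Of 32 ion, water and calcium genes, 9 rose and 5 fell (11 and 5 adjusted over the list alone; 0.0661), with the chloride channel ANO1 (1.88-fold) and the sodium channel subunit SCNN1G (1.71-fold) higher and the cotransporter SLC12A2 lower, at 1170 ± 397 and 663 ± 164 CPM. Of 34 adhesion genes, 9 rose and 1 fell (10 and 3 adjusted over the list alone; 0.0618), with LGALS3 (1.42-fold) and the integrins ITGA3 (1.52-fold), ITGA5 (1.41-fold) and ITGB6 (1.69-fold). Of 35 Wnt genes, 6 rose and 6 fell (8 and 7 adjusted over the list alone; 0.794): WNT7B, DKK3 (1.85-fold) and NKD2 (1.90-fold) rose, and the transcription factor LEF1 fell (log2 fold change -0.59 ± 0.06).

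Cholesterol synthesis was the list that changed downward in the main test. Its mean log2 ratio was 0.032, -0.316, -0.013 and -0.366 in mares 1 to 4, so the fall was mainly that of mares 2 and 4. Of 26 genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone), among them fatty acid synthase FASN (log2 fold change -0.41 ± 0.08), its regulator SREBF1 (-0.40 ± 0.08) and STARD4 (-0.85 ± 0.17). Its adjusted p was 0.0221, and adjusted p = 0.624 with an estimated correlation. The call was lost without mare 2 or 4, the highest adjusted p for cholesterol synthesis without a mare being 0.175. Of 28 cell cycle genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone; list adjusted p = 0.794), the helicase subunit MCM7 (1.34-fold) and, lower, CDC6, FOXM1 (passing in 11 of 16 alternatives) and UHRF1. Of 32 glycolysis and hypoxia genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; 0.185), among them NDRG1 (1.64-fold), PKM (1.37-fold) and ENO2 (1.42-fold).

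Of 58 ribosomal protein genes, 3 rose (0 adjusted over the list alone), RPLP1, RPL22 and RPL38 with folds of 1.22, 1.18 and 1.23, which passed in 7, 8 and 9 of 16 alternatives, in a list with adjusted p = 0.00525 and with adjusted p = 0.597 with an estimated correlation, and 0.122 without mare 4. Of 25 immediate early genes, 2 rose (2 adjusted over the list alone), FOSL2 (1.38-fold) and KLF6 (1.33-fold). That list had adjusted p = 0.0330, and adjusted p = 0.774 with an estimated correlation. It was also lost with library totals and without mare 1, and without mare 4 the median of immediate early genes was -0.14 and the adjusted p 0.985. Of 20 heat shock genes 3 rose (1 adjusted over the list alone; list adjusted p = 0.832), CRYAB from 6.31 ± 0.357 to 15.7 ± 4.26 CPM, HSPA2 and HSPB8, the last 2 near the threshold (adjusted p = 0.0402 and 0.0498; passing in 7 and 11 of 16 alternatives, up to 0.552 and 0.176), and of 27 unfolded protein response genes 1 rose (1 adjusted over the list alone; 0.794), the stress sensor ERN1 (1.50-fold). Of 15 genes of conceptus tissues, 3 rose (3 adjusted over the list alone): TEAD4 (1.77-fold), TFAP2C (2.04-fold) and APOB (1.71-fold; adjusted p = 0.0414), the last 2 passing in 12 and 8 of 16 alternatives (up to 0.0906 and 0.298). The conceptus list had adjusted p = 0.00447, and adjusted p = 0.362 with an estimated correlation. Further calls lost with 1 mare left out were those of SREBF1, PSMB8, PKM, FOSL2, KLF6 and TPPP3 (mare 1), CA12 (mare 1 or 2), UHRF1 (mare 1, 2 or 3), GZMK (mare 2) and ENO2 (mare 3). The median and the mean differed in sign for the Wnt, heat shock and unfolded protein response lists, and the test had the opposite sign to both for the steroid receptor list.

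The comparison between mares asked how far the animals differed apart from their state. CRYBG2 ranged from 1.93 CPM in the cyclic library of mare 1 to 65.9 CPM in that of mare 4, and from 1.59 to 46.7 CPM in the same mares in pregnancy. TMPRSS6, a membrane protease, was 47.9 and 49.9 CPM in mare 1 but 4.59 and 3.77 CPM in mare 3, in the cycle and in pregnancy. CTSL differed both between mares, from 55.1 CPM in mare 3 to 444 CPM in mare 4 in the cycle, and between states. These genes, from the 4 with the smallest p that carry a symbol, were named after their values were seen. In all, 2435 genes (15.9%) differed between mares, and 839 of them also changed with the state. Without mare 1 the count was 1103.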

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

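The outlying values of this part were found by a test fixed before the data were examined; which expression patterns to weigh was decided after the results were seen. For the chance tests below, all were planned.

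Within groups of 4 libraries, 11 values lay far from the other 3 by Dixon's ratio at its 95% critical value, out of 252 groups of values tested, where chance alone gives about 12.6. In the cycle these were MFAP4 in mare 3 (34.4 CPM; others 16.5 to 17.1), CMPK2 in mare 4 (6.94 CPM; 8.76 to 8.99), SLC12A2 in mare 2 (1763 CPM; 929.9 to 1020) and SCNN1G in mare 1 (51.6 CPM; 11.8 to 18.1). In pregnancy they were SPMAP2L in mare 2 (0.0645 CPM; 0.562 to 0.597), PGR in mare 2 (38.03 CPM; 24.4 to 25.2), IHH in mare 4 (780.1 CPM; 489.7 to 505.6), SRD5A3 in mare 4 (118.9 CPM; 90.0 to 90.4), PTGIS in mare 1 (76.7 CPM; 61.8 to 62.5) and RGS5 in mare 1 (93.9 CPM; 84.2 to 84.7). The remaining value was the total of the pregnant library of mare 1, 9.81 M against 16.4 to 16.7 M in the other pregnant libraries. PGR bears on a result: without mare 2, whose pregnant value stands out, its adjusted p was 0.0386.

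Exchanging the state labels within mares gives 8 arrangements, too few for a share under 0.05, since the smallest share is 0.125. The real arrangement called 2565 genes and the highest other 0, so 1 of 8 arrangements called as many. For gene lists the real arrangement called 17 and the highest other 15, again 1 of 8. The other arrangements called 4 to 15 lists while calling 0 genes, so the camera test with the preset correlation calls lists readily in these libraries, and its list calls are weak evidence. In the fit without the mare as replicate block, 1 of the 35 splits of the 8 libraries called as many genes, with 389 for the real split and 53 for the highest other. That split kept the libraries of whole mares together, and among the 8 splits that part all 4 mares the highest other called 0. This share is under 0.05 only if libraries of different mares can be exchanged freely; the 8 splits that respect the pairs are too few for such a share.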

How the results depend on the processing

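Thinning to the shallowest library and keeping the genes of the authors' scaled table were chosen after the results were seen; the other alternatives were fixed before the data were examined.

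The main count of 2565 genes (1309 higher, 1256 lower) fell to 389 (268 higher, 121 lower) with no replicate block, to 1119 (594 higher, 525 lower) at an adjusted p under 0.01 and to 360 (268 higher, 92 lower) at an absolute log2 fold change of at least 1. Leaving out 1 mare gave 1266 genes (653 higher, 613 lower) without mare 1 up to 2057 (1050 higher, 1007 lower) without mare 4. Library totals in place of TMM gave 2280 genes, 62.1% of them higher against 51.0%, so the balance of rises and falls depends on the scaling. Other scalings, filters and tools gave 2292 to 2620 genes. No gene of the main count that was called in an alternative had the opposite sign there.

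Of the lists, 17 passed in the main test, 0 with a correlation estimated per list, and 11 (without mare 4) to 19 (without mare 3) with 1 mare left out. Genes differing between mares numbered 2435, and 1103 (without mare 1) to 2049 (without mare 2) with 1 mare left out.

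Medians changed sign when a mare was left out for the unfolded protein response (-0.0715 to 0.0555), immediate early (-0.14 to 1.25), heat shock (-0.0761 to 0.0223), ciliated cell (-0.00499 to 0.17), Wnt (-0.0716 to 0.0489), cell cycle (-0.0341 to 0.0221) and steroid receptor lists (-0.0457 to 0.0376), and for the granulocyte list after thinning (-0.0267). With library totals the Wnt, cell cycle, heat shock and unfolded protein response medians were also above 0, and with the stricter filter the B and plasma cell median was below 0. Single genes that changed sign without a mare were PTGES (-0.0219 to 0.0516) and TPSB2 (-0.31 to 0.34), neither of which passed in the main test. Of 128 genes picked by the naming rule, 67 lost their call with no replicate block, 20 without mare 1, 16 without mare 2, 12 without mare 3 and 11 without mare 4.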

Other observations

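The tests on the share of epithelium, on a deeper biopsy and on transcripts of the endometrium itself were chosen only after the results were seen, as were the gene families; the other tests of this part were written before.

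Of the endothelial, stromal and smooth muscle markers, 17 of 22, 13 of 24 and 8 of 17 rose and 0, 1 and 1 fell; the 3 lists passed with the preset correlation and not with an estimated one (adjusted p = 0.356, 0.391 and 0.483). A smaller share of epithelium alone would raise the markers of every other cell type alike. The endothelial median exceeded the macrophage and dendritic median by 0.53 (95% interval 0.33 to 0.72) and in 4 of 4 mares. That pair was picked after the medians were seen, and the interval treats genes as independent, so the test cannot decide. Stromal, T and NK, and B and plasma cell medians lay between, at 0.43, 0.46 and 0.32, and the granulocyte median was 0.03. A smaller share of epithelium stays open. A deeper biopsy with more muscle and vessels could give the same joint rise: the lowest of the 12 medians over mares was 0.26, for smooth muscle in mare 4, with an interval from -0.13 to 0.44. Biopsy depth and a response of vessels and stroma to pregnancy cannot be told apart here, because each state of a mare has 1 biopsy.

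Of 15 conceptus genes tested 3 rose, and the list passed with the preset correlation but had adjusted p = 0.362 with an estimated correlation. For conceptus cells left after flushing as a candidate source, 15 other genes of the list, near absent in the cycle and too low to test, had a summed CPM 1.66 times as high in pregnancy, from 5, 5, 4 and 11 counts in cyclic mares 1 to 4 and 2, 5, 16 and 20 in pregnant ones. The higher sum came mostly from CYP11A1 in mare 3 and DLX3 in mare 4. CDX2, HAND1, AFP, APOA2, TTR, LIN28A and LIN28B had 0 counts in all 8 libraries. By the rule written before, the sums leave that source undecided. The 0 counts were no part of that rule and cannot exclude a small admixture at this depth. The called members TEAD4, TFAP2C and APOB were expressed in every cyclic library, the lowest value being 0.880 CPM for APOB, which is consistent with transcripts of the endometrium itself, while a small contribution of conceptus cells stays open.

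Fallers had longer genes, with a median span of 53.8 kb against 27.5 kb for risers and 23.7 kb for genes that did not pass. A loss of reads from long genes shared by the pregnant libraries was to show as a Spearman correlation below -0.1 in every mare. The correlation of log2 ratio with span over 14266 genes was -0.0956, -0.0659, 2.66e-04 and -0.142 in mares 1 to 4 and -0.0909 over all. This argues against a loss with span of that size in all 4, while a weaker loss, or one in some libraries, stays open. Span is the genomic distance from start to end and not the length of the transcript. A loss of reads that follows transcript length was therefore not tested. A fall of zinc-finger genes as a class was also not seen by the rule set for it. Their median of -0.0125 over 258 genes lay above the 2.5th percentile of random lists matched on span and expression (-0.0176). It lay close to that limit, with 514 of 10000 lists as low. What makes fallers longer stays open, and no biological explanation was tested.

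Some of 10 gene families held members that moved both ways. Of 16 keratins, KRT17 (log2 fold change 2.29) and KRT80 (0.81) rose while KRT4 (-1.45), KRT78 (-1.39), KRT7 and KRT18 fell. Of 38 proteasome subunits, those that rose were the immunoproteasome genes PSMB8, PSMB9 and PSMB10. Zinc-finger genes held fewer risers than other genes (4 of 258, adjusted p = 5.30e-05 by Fisher's exact test over 20 tests). Fisher's test treats genes as independent and is not matched on span or expression, so its p does not measure variation between mares. Of the 258, 21 fell, which is no excess beside 1256 of 15342 genes in all. No other of these 20 tests passed, the next lowest adjusted p being 0.134. Of 18 subunits of the vacuolar proton pump, ATP6V0A4 and ATP6V0D2 rose, and ATP6V1A, ATP6V1B2 and ATP6V0A2 fell.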
